A study of Mus musculus with 3 samples.

How the data were processed

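The study sequenced total RNA, extracted with Trizol, from inguinal lymph nodes of male C57BL/6j mice, 1 library in each of 3 groups, which were taken from the agent named in the sample labels. Whether a library came from 1 animal or from several is not given in the sources used here. Female mice named in the series description were not analysed here. The labels name no sequencing batch.

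Per the submitters' processing notes, STAR 2.7.0c, Cufflinks 2.2.1, Cuffdiff and Cuffnorm were used with the mouse build GRCm38; the role of each tool, its settings and the annotation release are not given in the sources used here. The deposited table gives, for 46951 loci, an FPKM value (fragments scaled by transcript length and library size) and a normalized count signal per library, as the authors named the columns. Its FPKM sums were 581683, 664536 and 649447 in the control, 20(OH)D3 and 25(OH)D3 libraries. The deposited normalized count signal behaved as whole reads multiplied by 1 factor per library, 0.938, 1.05 and 1.01. Dividing by the factor gave values within 0.02 of a whole number for 99.9% of loci in each library, and these are called reads here. The factor of the 25(OH)D3 library is so near 1 that this recovery is less certain for it. Loci with at least 1 read numbered 20362, 21031 and 20257.

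A locus merges overlapping genes, and 1064 loci carry more than 1 symbol. C2 shares its locus with Cfb, and mt-Nd1 with ribosomal RNA genes of the mitochondrion. FPKM depends on how fragments were shared among isoforms, so the FPKM ratio of a locus can depart from its count ratio. Whether counting used strand is not given, and near-identical copies, such as the globin, immunoglobulin and histone genes, can exchange reads. Of 13 mitochondrially encoded messages, 10 were listed at 0 in all libraries, so a listed 0 can be a failed estimate. Of the table's lines, 2 were empty as analysed here, and 7 list symbols were not found and were not analysed here. Coordinates are those of the table, counted from 1.

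The design was fixed before the data were examined. For each comparison the log2 ratio of (FPKM + 1) was computed for 14032 loci with a mean of at least 1 FPKM over the 3 libraries, and loci at least 2-fold higher or lower were counted. This scale understates the ratios of low genes. No test across genes was run, since 1 library per group leaves no estimate of spread, and no count model was fitted to the recovered reads for the same reason. A set of 57 gene lists with 717 different symbols covered targets of the treatment, immune programmes, cell types of the node, neighbouring tissues, metabolism and general processes, and 34 symbols stood in more than 1 list. For the 50 lists with at least 5 members past the filter, the median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of like mean expression, and a list outside the central 95% (below percentile 2.5 or above 97.5) was called. These percentiles describe the libraries and are not p-values. Bootstrap intervals of list medians, from 10000 draws of the members, were added after the data were seen and cover the spread among members.

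Genes were named by rule. In each comparison these are the 12 highest and 12 lowest log2 ratios among loci with a mean of at least 5 FPKM, leaving out immunoglobulin and T cell receptor segments, predicted or clone-named models, pseudogenes and small RNA genes. List members with the extreme ratios or a 2-fold difference may be named as examples, and Vdr, Cyp24a1 and Cyp27b1 always. Other members of a list that are named, such as Adipoq, Csf3r, Ddx3y and the heavy chain genes within 2-fold, were chosen after their values were seen. Ratios of normalized counts were added with exact 95% (Clopper-Pearson, conditional on the sum of both counts) intervals, which cover counting error only, since reads without molecular identifiers are not independent molecules.

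The alternatives fixed beforehand were pseudocounts of 0.1 and 5 FPKM, no expression filter or a mean of at least 5 FPKM, rescaling to TPM, by the median of ratios or to the upper quartile, removal of immunoglobulin, mitochondrial and small RNA genes before rescaling to TPM, and a 3-fold threshold. Normalized counts with a pseudocount of 10 in place of FPKM, a minimum of 20 reads, leaving out the fat lists, and taking a running median over transcript length off the list ratios were added after the data were seen. Rescaling to TPM moved the median log2 ratio over loci from -0.01 to -0.18 for 20(OH)D3 and from 0.03 to -0.12 for 25(OH)D3 against the control. List calls are relative to random lists and so to this shift.

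The procedure was tested on libraries simulated with counting error only, with 200 changed loci among 14032. Variation between mice, the sharing of fragments among isoforms and co-regulation of list members were not simulated. The observed log2 normalized count ratios of 20(OH)D3 to the control had an SD of 0.402, against 0.128 with counting error only. The shares below thus hold for counting error alone and are likely too favourable for these libraries. In the simulation of 20(OH)D3 against the control, 93% of 4-fold and 72% of 2.5-fold changes were recovered, 1.03% of unchanged loci passed 2-fold by counting error, 6% of random lists were called, and 96.0% of the counting intervals held the true ratio. For 25(OH)D3 against the control the recovered shares were 94% and 75%, and between the compounds 93% and 73%. Transcript lengths came from GENCODE M21 for GRCm38. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.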

Results

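RNA was sequenced from inguinal lymph nodes of male C57BL/6j mice, with 1 library for each of 3 groups. All mice had received dinitrofluorobenzene (DNFB), a contact sensitizer, on the abdominal skin. Intraperitoneal injections began 3 days later with the ethanol vehicle, with 20(OH)D3 or with 25(OH)D3. Both compounds are monohydroxylated derivatives of vitamin D3 that differ in the side-chain carbon bearing the hydroxyl group, and both were given at 4 µg/kg per day. The sample labels give 4 consecutive daily injections and collection 24 hours after the last one, whereas the series description gives 1 week of treatment. Reads recovered from the normalized counts totalled 8226431 in the control library, 7522550 in the 20(OH)D3 library and 7991748 in the 25(OH)D3 library. With 1 library per group no difference had a replicate check, no p-value could be given, and each value describes these libraries rather than the treatments. Intervals beside ratios of normalized counts are 95% exact intervals and cover counting error only. The libraries carried the messages of male cells, with 1039, 865 and 992 reads of Ddx3y and 4, 7 and 16 reads of Xist in the control, 20(OH)D3 and 25(OH)D3 libraries.

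The first comparison asked how nodes of the 20(OH)D3 group differed from vehicle. Fat genes were far higher in the 20(OH)D3 library. The adipocyte list had a median log2 ratio of 1.72, with 18 of 18 members above 0 and 17 at least 2-fold higher, beyond all 10000 random lists of like expression. The adipokine Adipoq stood at 107 FPKM in the control and 471 FPKM in the 20(OH)D3 library, a normalized count ratio of 4.40 (interval 4.12 to 4.70). Fabp4, the fatty acid carrier of adipocytes, stood at 877 and 3461 FPKM, a ratio of 3.95 (3.84 to 4.07). Cfd, or adipsin (GRCm38 chromosome 10, 79890853 to 79892656), stood at 607 and 3591 FPKM, a ratio of 5.91 (5.72 to 6.11). Lpin1 had the smallest ratio of the list, 1.26 (1.13 to 1.40). The brown fat list had a median log2 ratio of 1.58, with 4 of 6 members at least 2-fold higher. Ucp1, the uncoupling protein of brown and beige adipocytes, stood at 12.4 and 44.3 FPKM, and Cox8b at 66.1 and 373 FPKM.

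**Figure D1:**
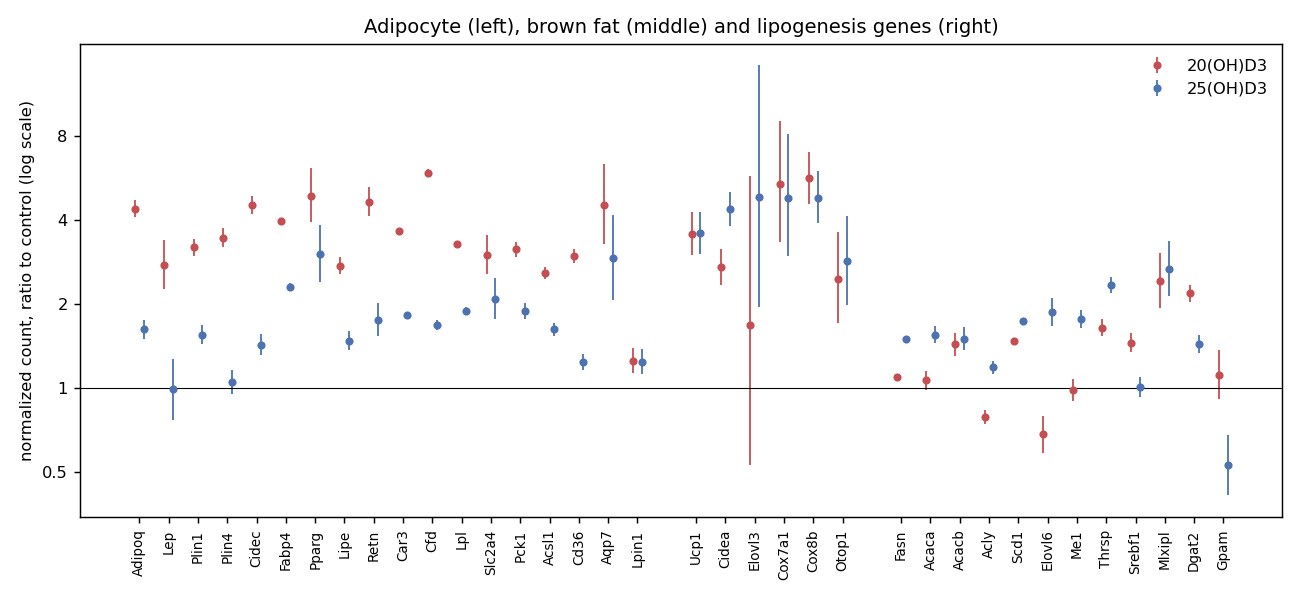
Ratio of the normalized count in each treated library to the control (log axis) for adipocyte, brown fat and lipogenesis genes, as points with 95% counting intervals. The adipocyte points of 20(OH)D3 lie mostly above those of 25(OH)D3, with Adipoq at 4.40 and 1.62 and Lep at 2.77 and 0.993.

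Several other groups stood higher in the same library. Erythroid genes had a median log2 ratio of 1.29 with 4 of 6 members at least 2-fold higher, among them the beta globin gene Hbb-bs (22.5 and 90.5 FPKM). Nuclear genes of the respiratory chain were above 0 in 21 of 21 members, with a median of 0.49, the largest ratios in Cox6c (225 and 861 FPKM) and Ndufa4 (136 and 455 FPKM) and the smallest in Sdha (104 and 106 FPKM). Fibroblastic reticular and collagen genes had a median of 0.45 with 13 of 16 members above 0. Their extremes were Lum, a collagen-binding proteoglycan (3.07 and 14.4 FPKM), and the T-zone chemokine Ccl19 (5.81 and 2.87 FPKM). Dpt was also over 2-fold higher (16.8 and 54.4 FPKM). Macrophage markers had a median of 0.42 with 13 of 15 members above 0, and C1qb was at least 2-fold higher (144 and 337 FPKM) while Vcam1 was lowest (67.9 and 62.0 FPKM). The complement list had a median of 0.54 and shares its C1q genes with the macrophage list and Cfd with the adipocyte list. Natural killer cell markers had a median of 0.50, which came inside the random range when genes were required to average 5 FPKM. Interferon gamma-induced genes had a median of 0.30, with Socs1 (14.6 and 40.2 FPKM) and the GTPase Iigp1 (21.6 and 54.0 FPKM) at least 2-fold higher and Cxcl10 lowest (19.7 and 14.7 FPKM). Cholesterol synthesis genes had a median of 0.20.

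Lymphocyte genes stood lower in the 20(OH)D3 library, by small amounts. Both scales are relative to the rest of the library. Here and between the compounds, fewer lymphocytes thus cannot be told from a larger share of other tissue, such as fat. T cell markers had a median log2 ratio of -0.33 with 15 of 18 members below 0. The transcription factor Lef1 was lowest (70.0 and 44.6 FPKM) and Cd2 highest (188 and 207 FPKM). B cell markers had a median of -0.23 with 15 of 18 members below 0, from Pax5 (90.3 and 60.3 FPKM) to Cd79a (656 and 715 FPKM). Migratory dendritic cell markers had a median of -0.26 with 11 of 12 members below 0, and Apol7c was lowest (127 and 88.5 FPKM). Germinal centre B cell genes had a median of -0.32, a call that was lost when genes were required to average 5 FPKM.

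Single genes at the head of the ranking included Ifi27l2a, an interferon-stimulated gene (chromosome 12, 103442167 to 103443680), at 386 and 3057 FPKM, a ratio of 7.89 (7.39 to 8.44). It stood apart from its list, since the interferon-stimulated genes had a median log2 ratio of 0.13 with 13 of 20 members above 0, inside the random range. The imprinted gene Nnat stood at 41.7 and 242 FPKM, haptoglobin (Hp) at 56.6 and 376 FPKM, and the thiosulfate sulfurtransferase Tst at 7.54 and 55.2 FPKM. Whether such single genes follow the fat content of the library was not tested. Wfdc21 rested on few reads, 4 in the control and 147 in the 20(OH)D3 library, a ratio of 41.1 (15.7 to 153). Fcor, Proca1 and S100a8 also ranked among the 12 highest, with 9, 11 and 9 reads in the control and 66, 80 and 58 in the 20(OH)D3 library. At the other end stood the class-switched heavy chain genes Ighg1 (80.5 and 17.1 FPKM, 4.61-fold lower in counts, interval 3.86 to 5.52) and Ighe (12.3 and 2.65 FPKM, 4.64-fold lower, 3.03 to 7.36). Ighg1 encodes the constant region of IgG1 and Ighe that of IgE. Of the other heavy chain genes, Ighg3 (57 and 187 reads), Ighg2b (113 and 218 reads) and Igha (14 and 33 reads) stood higher, while Ighm and Ighd had count ratios of 0.862 (0.843 to 0.880) and 0.833 (0.812 to 0.854). The protease inhibitor Slpi (10.9 and 4.00 FPKM), Rgs11 (8.74 and 2.75 FPKM), Cep85 (108 and 51.3 FPKM), Zrsr2 (22.9 and 10.8 FPKM) and the nuclear noncoding RNA Malat1 (630 and 293 FPKM) were also among the 12 lowest. For Malat1 the normalized counts gave 1.48-fold lower (1.43 to 1.53). The counts did not bear out the size of several FPKM ratios. Of the 12 highest genes 10 also passed 2-fold on normalized counts, and of the 12 lowest 4. Cep85 was 1.77-fold and Zrsr2 1.70-fold lower by counts. Ptp4a1 was 26.3-fold higher by FPKM and 1.76-fold by counts, Mfn1 2.38-fold lower by FPKM and 1.08-fold by counts, and Tmco5b, listed at 0 in the other libraries, had 2 reads.

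By the fixed rule, 620 of 14032 loci were at least 2-fold higher and 159 at least 2-fold lower in the 20(OH)D3 library, and on normalized counts 418 and 31. On both scales 343 were higher and 20 lower. Loci of the classes left out of naming made up 210 of the 620 and 129 of the 159, and 145 and 90 had under 20 reads. Unchanged libraries simulated with counting error only gave 78 higher and 79 lower. The share of higher among these calls was 79.6%, against 63.9% after rescaling to TPM, 67.1% after also removing immunoglobulin, mitochondrial and small RNA genes, and 93.1% on normalized counts. Of 50 lists tested, 10 lay above and 4 below the central 95% of random lists. Among these the natural killer cell list had a bootstrap interval over its members that held 0 (-0.02 to 0.66).

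**Figure D2:**
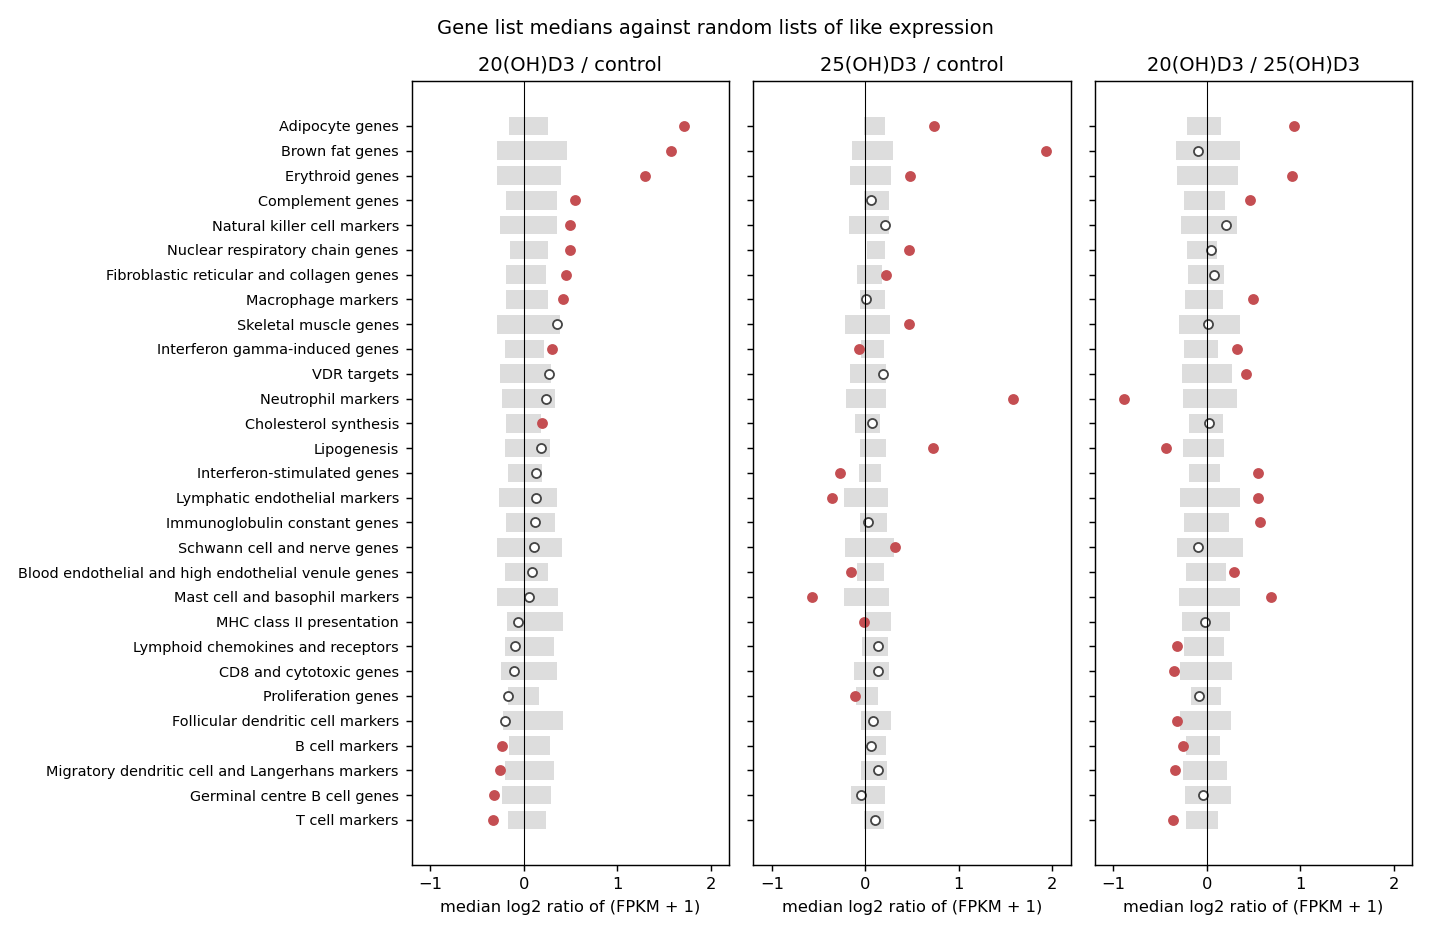
Median log2 ratio of (FPKM + 1) for each gene list that left the random range in at least 1 comparison, with grey bars for the central 95% of 10000 random lists and filled points for lists outside it. Adipocyte genes stood at 1.72, 0.73 and 0.94, and brown fat genes at 1.58, 1.93 and -0.10 in the panels from left to right.

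The second comparison set 25(OH)D3 against vehicle. Brown fat genes had the highest list median, 1.93, with 6 of 6 members at least 2-fold higher. Cidea, a lipid droplet protein of brown adipocytes, stood at 28.4 FPKM in the control and 125 FPKM in the 25(OH)D3 library, a ratio of 4.38 (3.82 to 5.04). Ucp1 (chromosome 8, 83290352 to 83298452) stood at 12.4 and 44.8 FPKM, a ratio of 3.59 (3.02 to 4.29). Cox8b had a ratio of 4.81 (3.90 to 5.98) and Cox7a1 of 4.80 (2.97 to 8.12). Adipocyte genes had a median of 0.73 with 17 of 18 members above 0, from Pparg at 3.03 (2.40 to 3.86) to the leptin gene Lep at 0.993 (0.773 to 1.28). Lipogenesis genes had a median of 0.72 with 11 of 12 members above 0. Thrsp was highest (132 and 310 FPKM), fatty acid synthase Fasn was at 413 and 850 FPKM, though less far apart by counts, with 9923 and 13839 reads, and the acyltransferase Gpam was lowest (5.96 and 3.17 FPKM). Nuclear respiratory chain genes were above 0 in 21 of 21 members with a median of 0.47, led by cytochrome c, Cycs (19.7 and 39.9 FPKM). The locus of mt-Cytb, a mitochondrially encoded message, stood at 8271 FPKM in the control, 12018 FPKM in the 20(OH)D3 library and 16331 FPKM in the 25(OH)D3 library. Mitochondrial loci took 2.12%, 2.93% and 3.95% of the normalized counts of these libraries. These shares do not measure mitochondrial messages as a whole. Of 13 mitochondrially encoded messages 10 were listed at 0, and mt-Nd1 shares its locus with ribosomal RNA genes.

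Neutrophil markers had a median log2 ratio of 1.59 with 6 of 11 members at least 2-fold higher, all on low counts. The granule protein gene Ngp had 8 reads in the control and 102 in the 25(OH)D3 library, a ratio of 13.7 (6.69 to 32.5). The cathelicidin gene Camp had 3 and 47 reads, S100a8 9 and 91, and S100a9 24 and 109. Csf3r, the receptor of the granulocyte growth factor, had 153 and 141 reads. Schwann cell genes (median 0.32) also lay above the random range, as did erythroid genes (0.47) and fibroblastic and collagen genes (0.22), whose members disagreed more, with bootstrap intervals of -0.20 to 0.74 and -0.07 to 0.27. Skeletal muscle genes did so (0.47) by FPKM and not by normalized counts.

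Interferon-stimulated genes stood lower in the 25(OH)D3 library, with a median log2 ratio of -0.27 and 18 of 20 members below 0. Ifi44 was lowest (6.19 and 3.33 FPKM, ratio 0.510, interval 0.375 to 0.687) and Ifi27l2a was highest (386 and 495 FPKM). Interferon gamma-induced genes had a median of -0.06. Mast cell and basophil markers had a median of -0.57 with 5 of 6 members below 0, from the mast cell protease Mcpt4 (182 and 83 reads) to Kit (7.16 and 8.68 FPKM). Lymphatic endothelial markers had a median of -0.36 with 7 of 8 members below 0, and Mmrn1 was lowest (2.18 and 0.888 FPKM). Blood endothelial genes (-0.15) and proliferation genes (-0.11) lay just below the random range. The MHC class II list did so too, but its median of -0.01 became 0.02 on normalized counts. T cell (0.10) and B cell markers (0.06) lay inside the random range.

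Among single genes Ighg1 was lowest, at 80.5 and 2.76 FPKM, 16.4-fold lower in counts (12.1 to 22.7), and Ighe had 135 and 5 reads, 25.2-fold lower (10.5 to 78.8). Jchain, which links IgM and IgA multimers, was 3.73-fold lower (2.98 to 4.70), and Ighg2c 2.95-fold lower (2.07 to 4.28). Slpi (10.9 and 2.69 FPKM) and the matricellular protein gene Cyr61 (9.67 and 2.84 FPKM) followed. Slc15a2, a peptide transporter gene, was listed at 12.4 FPKM in the control, 7.13 FPKM in the 20(OH)D3 library and 0 in the 25(OH)D3 library. A listed 0 is not read as absence, because 10 of 13 mitochondrially encoded messages were also listed at 0 in all 3 libraries. Eps8l1, a gene of the actin-regulating Eps8 family, was 3.83-fold higher in counts (3.25 to 4.54). The FPKM of Adgre5, a leukocyte adhesion receptor, was 8.64-fold higher while its normalized count ratio was 0.965 (0.905 to 1.03). Hotairm1 rested on 15 and 23 reads and Snhg7 on 1 read.

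**Figure D3:**
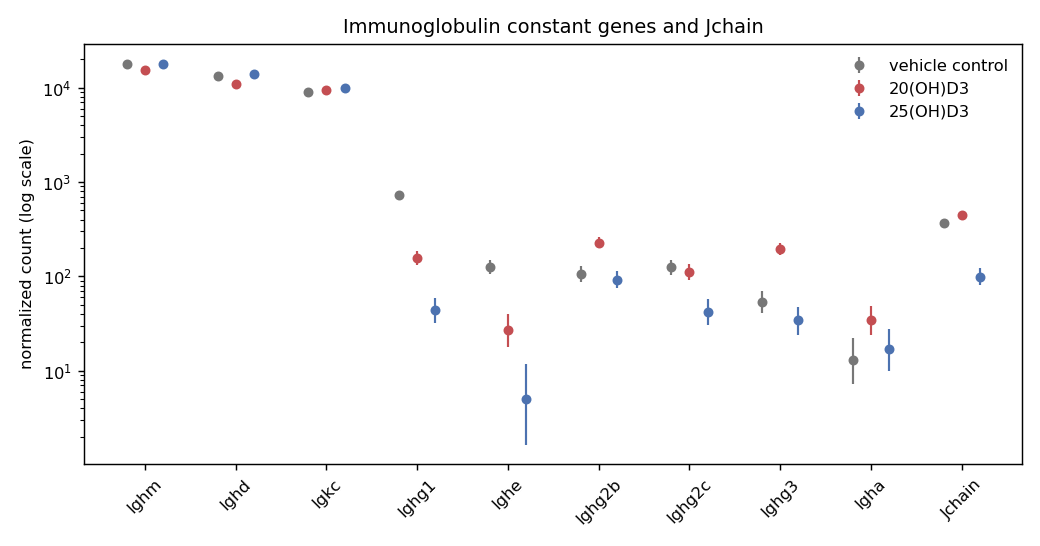
Normalized counts of immunoglobulin constant genes and Jchain in each library (log axis), with 95% counting intervals. Ighg1 had 773, 150 and 44 reads and Ighe 135, 26 and 5 reads in the control, 20(OH)D3 and 25(OH)D3 libraries, while Ighm had 19224, 14803 and 17758 reads.

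In this comparison 190 loci were at least 2-fold higher and 143 at least 2-fold lower, and on normalized counts 70 and 30. On both scales 59 were higher and 18 lower. Loci of the classes left out of naming made up 107 of the 190 and 120 of the 143, and 79 and 88 had under 20 reads. Unchanged libraries simulated with counting error only gave 64 higher and 81 lower. The share of higher among these calls was 57.1%, against 43.0% after rescaling to TPM and 70.0% on normalized counts. Of 50 lists, 9 lay above and 7 below the random range. The bootstrap interval over members held 0 in 6 of these, which are the erythroid, fibroblastic, skeletal muscle, interferon gamma-induced, blood endothelial and MHC class II lists.

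The third comparison set the compounds against each other at the same dose and time. Adipocyte genes were higher with 20(OH)D3 in 18 of 18 members (median 0.94), from Cfd at 3.51 (3.41 to 3.61) to Lpin1, whose interval of 0.915 to 1.12 held 1. The brown fat list did not leave the random range, with a median of -0.10, and Ucp1 had a ratio of 0.993 (0.880 to 1.12). Lipogenesis genes were higher with 25(OH)D3 in 9 of 12 members (median -0.44), and Elovl6 was 2.73-fold lower with 20(OH)D3 (2.38 to 3.14). Interferon-stimulated genes were higher with 20(OH)D3 in 16 of 20 members, with a median of 0.55. Ifi27l2a had a ratio of 6.29 (5.91 to 6.69), Ifi44 of 2.51 (1.87 to 3.38) and Isg15 of 2.10, whereas Mx1 had a ratio of 0.623 (0.528 to 0.732). Interferon gamma-induced genes had a median of 0.32, with Iigp1 at a ratio of 2.98 (2.67 to 3.33). Erythroid genes (0.91), mast cell and basophil markers (0.69), lymphatic (0.55) and blood endothelial genes (0.29), macrophage markers (0.50) and complement genes (0.47) were also higher with 20(OH)D3.

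Immunoglobulin constant genes had a median of 0.56 between the compounds (bootstrap interval over members -0.07 to 1.38), with 5 of 12 members at least 2-fold higher with 20(OH)D3. Ighg3 had a ratio of 5.74 (3.96 to 8.53), Ighg1 of 3.56 (2.53 to 5.10) and Jchain, outside that list, of 4.45 (3.56 to 5.59). Nnat (8.28, interval 7.28 to 9.45), Sncg (6.18, 4.86 to 7.94), the cytochrome gene Cyp2f2 (6.78, with 221 and 34 reads) and the amino acid transporter gene Slc7a10 (5.73, 4.35 to 7.65) stood high in the 20(OH)D3 library alone. The adipocyte list was also highest in this library, and whether these genes follow its fat content was not tested. T cell markers were lower with 20(OH)D3 in 17 of 18 members (median -0.37), B cell markers in 17 of 18 (-0.26, inside the random range at -0.21 once a trend with transcript length was taken off), migratory dendritic cell markers in 10 of 12 (-0.34) and CD8 and cytotoxic genes in 6 of 9 (-0.35, bootstrap interval -0.45 to 0.26). In the last list Gzma, a cytotoxic granule protease, went the opposite way at 3.41 (2.39 to 4.96), and the list came inside the random range without the expression filter. Neutrophil markers, on low counts, were lower too (-0.88, and -0.52 on normalized counts). Lymphoid chemokines and receptors and follicular dendritic cell markers (both -0.32) lay below the random range with bootstrap intervals over members that held 0 (-0.39 to 0.24 and -0.42 to 0.00). Cep97, Ggt1, Cep131 and Zfp94 were among the 12 lowest by FPKM, with count ratios of 0.542, 0.636, 0.709 and 0.544. The rule gave 449 loci at least 2-fold higher and 171 lower, and on normalized counts 273 and 47. On both scales 207 were higher and 29 lower. Loci of the classes left out of naming made up 201 of the 449 and 119 of the 171, and 144 and 88 had under 20 reads. The share of higher was 72.4%, against 67.6% after rescaling to TPM, 65.6% after also removing immunoglobulin, mitochondrial and small RNA genes, and 85.3% on normalized counts. Of 50 lists, 11 lay above and 8 below the random range.

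Genes of vitamin D signalling were near the detection limit. The receptor gene Vdr had 34, 24 and 16 reads in the control, 20(OH)D3 and 25(OH)D3 libraries, under 1 FPKM in each. Cyp24a1, the catabolic hydroxylase induced by the active hormone, had 4 reads in the 20(OH)D3 library and was listed at 0 in the control and 25(OH)D3 libraries. Cyp27b1, the activating hydroxylase, had 3 and 4 reads and was listed at 0 in the 25(OH)D3 library. Differences in these genes between the libraries were not detectable at this depth, except that the Vdr count was 1.98-fold lower with 25(OH)D3 than in the control (1.06 to 3.84). The list of 15 genes taken here as targets of the receptor had 9 members past the filter. It stayed inside the random range against the control, at 0.27 for 20(OH)D3 and 0.19 for 25(OH)D3. On normalized counts the 20(OH)D3 median was 0.29 and lay above the range. Between the compounds the list lay above it (0.42), but its bootstrap interval over members held 0 (-0.57 to 0.67) and its mean was 0.04. Camp, which is also named above among the neutrophil markers, went far the other way. Cebpb, a transcription factor, stood at 16.8, 56.1 and 23.0 FPKM. The adipocyte list had the same order over the libraries, and whether Cebpb follows their fat content was not tested.

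Across 14032 loci the log2 ratios of both compounds to the control had a Pearson r of 0.44 and a Spearman rho of 0.38, over genes that are not independent replicates. Both ratios share 1 control library. Unchanged libraries simulated with counting error only gave an r of 0.47, with a covariance of 0.0474 against an observed 0.108. Calls at least 2-fold higher overlapped in 94 loci, against 8.40 for independent lists and 23 in the simulation. Calls at least 2-fold lower overlapped in 48, against 1.62 and 30. The simulated lists were smaller, with 78 and 64 loci higher against 620 and 190 observed, and 79 and 81 lower against 159 and 143. Relative to list size, the overlap of lower calls was no larger than in the simulation. For higher calls the overlap was larger than simulated relative to the smaller list, but not relative to the size of both lists together. On normalized counts 45 higher and 9 lower calls overlapped, against 2.09 and 0.0663 for independent lists. Variation between mice is not in the simulation, so the shared control may account for more of the overlap than was simulated. Over the 9898 loci with a mean of at least 5 FPKM the 20(OH)D3 library stood farthest apart, with an SD over genes of the log2 normalized count ratio of 0.402 against the control and 0.354 against 25(OH)D3, while 25(OH)D3 against the control gave 0.262.

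**Figure D4:**
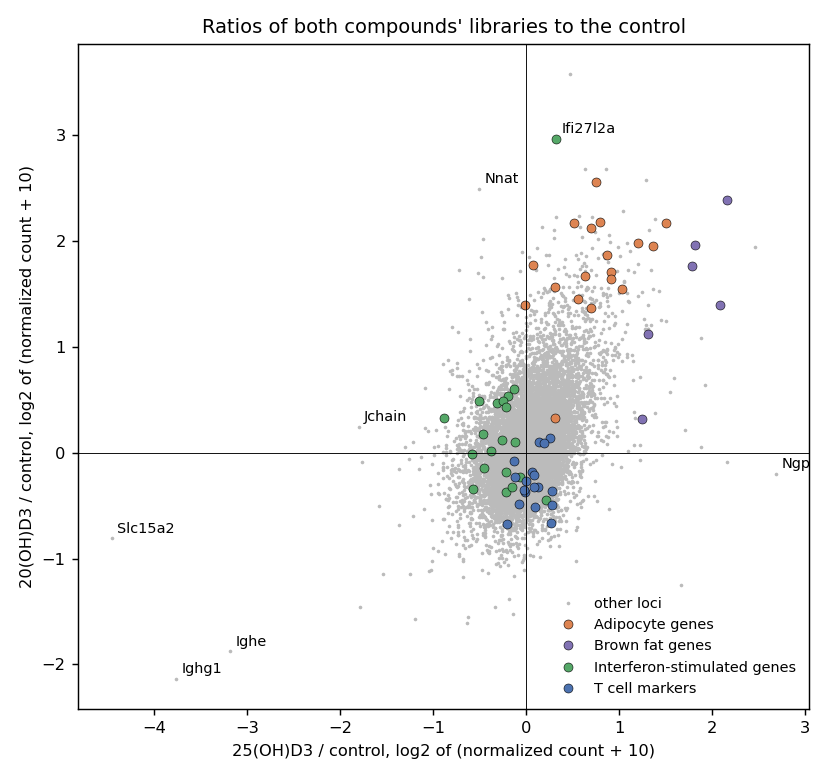
Log2 ratio of (normalized count + 10) to the control for 25(OH)D3 (horizontal) and 20(OH)D3 (vertical), 1 point per locus, with 4 gene lists in colour. Adipocyte and brown fat genes lie at the upper right, Ighg1 and Ighe at the lower left, and Slc15a2, at the far left, is listed at 0 in the 25(OH)D3 library.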

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

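The alternatives with normalized counts, a minimum of 20 reads, the fat lists left out and the length trend taken off were chosen after the data were seen. No paired analysis was possible because each group holds 1 library, and for the same reason no library could be left out in turn. The number of lists above and below the random range was set against its reported value under 9 alternatives. These leave out the 3-fold threshold, the 20-read minimum, the fat lists left out and the length trend. It stayed within 1.5 times that value in 54 of 54 counts, though the lists tested numbered from 42 to 55. The correlation of the ratios of both compounds to the control stayed between 0.43 and 0.47 in all 9. The number of loci at least 2-fold apart depended on the settings in 38 of 72 alternatives, and the cause was not tested.

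Against reported values of 620 higher and 159 lower (20(OH)D3 against control), 190 and 143 (25(OH)D3 against control) and 449 and 171 (20(OH)D3 against 25(OH)D3), the counts that moved by over 1.5 times were these. A pseudocount of 0.1 FPKM gave 321 lower in the first comparison, 359 higher and 288 lower in the second, and 711 and 341 in the third. A pseudocount of 5 FPKM gave 272 and 33, then 61 and 34, then 139 and 40. Without an expression filter the lower counts were 272, 242 and 275. A mean of at least 5 FPKM gave 379 and 47, 84 and 44, and 205 and 51. Rescaling to TPM gave 295 lower in the first comparison and 249 in the second, and removing immunoglobulin, mitochondrial and small RNA genes as well gave 257 lower in the first. A 3-fold threshold gave 199 and 58, 63 and 58, and 145 and 66. Normalized counts gave 31 lower in the first comparison, 70 and 30 in the second, and 273 and 47 in the third. A minimum of 20 reads gave 69 lower, 111 and 55, and 83 lower. Leaving out the fat lists moved no count by over 1.5 times, with 598 higher and 159 lower in the first comparison.

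A pair of results changed sign, both on normalized counts and both for 25(OH)D3 against the control. The MHC class II median became 0.0155 and the log2 ratio of Adgre5 -0.0515; the cause was not tested. The MHC class II list also came inside the random range there, as did 4 other list medians under some alternative, while 22 moved outside it. With the length trend taken off, 1 further call was lost and 14 were gained over the 3 comparisons, and the lists below the random range for 20(OH)D3 against the control went from 4 to 8; the cause was not tested. Depth limits low genes most, since 145 of the 620 higher and 90 of the 159 lower loci of the first comparison had under 20 reads.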

Other observations

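The tests on list calls after the length trend, the IgG genes, plasma cells, the kind of fat and the fat share behind the interferon genes were chosen after the results were seen; the others were fixed before the result they measure.

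Short transcripts stood higher in both treated libraries than in the control. Both ratios share this 1 control library, so a shift in the control alone cannot be told from a shift in both treated libraries. Over 11773 loci with an annotated protein-coding length, the log2 ratio had a Spearman rho with transcript length of -0.28 for each compound against the control and -0.10 between the compounds. In the shortest decile (up to 1282 nt) the median log2 ratio was 0.35 for 20(OH)D3 and 0.19 for 25(OH)D3, and in the longest (from 6594 nt) -0.12 and -0.06. After the running median over genes of like length was taken off, nuclear respiratory chain genes kept medians of 0.34 and 0.32, and cytosolic ribosomal protein genes went from 0.11 to -0.23 and from 0.11 to -0.07. Of 48 calls with lengths, 28 had a median nearer 0 after this step and 20 one farther from it, such as fibroblastic and collagen genes for 20(OH)D3 (0.45 to 0.51) and lipogenesis genes for 25(OH)D3 (0.72 to 0.76). For 25(OH)D3 erythroid genes went from 0.47 to 0.23 and skeletal muscle genes from 0.47 to 0.31, and for 20(OH)D3 complement genes went from 0.54 to 0.35 and macrophage markers from 0.42 to 0.28. Fibroblastic and collagen genes for 25(OH)D3 went from 0.22 to 0.15. Set against random lists of the corrected ratios, 14 of 14 calls for 20(OH)D3 against the control, 16 of 16 for 25(OH)D3 against the control and 17 of 18 between the compounds were kept, the immunoglobulin constant list being left out because only 1 of its 12 members had a length, and the B cell markers between the compounds came inside the range (-0.21). Erythroid genes for 25(OH)D3 were kept narrowly, with an upper end of the random range of 0.22. In the same order 6, 5 and 3 further lists moved outside, among them vitamin D receptor targets (0.24) and plasma cell genes (-0.15) for 25(OH)D3. Replication-dependent histone genes, also short, had 4 members past the filter, too few to test, with medians of 0.70 for 20(OH)D3 (4 above 0) and 0.59 for 25(OH)D3 (3 above 0).

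Adipocyte genes were higher in the 20(OH)D3 library than in the control, and a candidate explanation is more fat tissue around the collected node. A second list of 18 adipocyte genes, fixed before its values were seen, had a median log2 ratio of 1.2088, with 18 of 18 members above 0, above the bound of 0.86 that was written beforehand for this explanation. The script at first asked the interval's lower end, 0.85, to pass that bound, which left the test undecided, and was changed after the value was seen to use the median as written. A trend with transcript length was too small to be the whole source. Its medians were 0.35 in the shortest and -0.12 in the longest decile, and the first list's median was 1.7181 after it was taken off. In the 25(OH)D3 library the brown fat median exceeded the adipocyte median by 1.2019 (95% bootstrap interval 0.36 to 1.62). This met the bound written against a larger amount of the same kind of fat. That bound was written after both medians were seen, and the interval covers co-regulated members of 1 library pair. No conclusion on the kind of fat is drawn from it. Fat of another kind, and an effect of the compounds on fat in or beside the node, stay open, because each group has 1 library and dissection cannot be told from treatment.

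Ighg1 and Ighe were lower in both treated libraries. Reads moving between the similar IgG genes could lower Ighg1 alone and would leave the sum of these genes unchanged. The normalized counts summed over 4 IgG genes were 0.6873 of the control in the 20(OH)D3 library (interval 0.623 to 0.758). This lay between the bounds written for and against the explanation. Moved reads stay undecided there as a part of the difference, but they would not lower the sum. In the 25(OH)D3 library the sum was 0.2114 (0.182 to 0.245), where the loss is too large for moved reads. For the 20(OH)D3 sample the plasma cell median was 0.0489 and the Jchain ratio 1.19 (1.04 to 1.37). The median carries little weight, since it was also near 0 in the 25(OH)D3 sample, where Jchain was far lower. The Jchain ratio goes against fewer plasma cells in the 20(OH)D3 sample, but it rests on 1 gene. In the 25(OH)D3 sample the plasma cell median was 0.0135 (-0.15 with the length trend taken off) while the Jchain ratio was 0.268 (0.213 to 0.335). There Mzb1, Sdc1 and Derl3 had ratios of 1.02, 0.73 and 0.76, with intervals that held 1. Fewer plasma cells in that sample thus cannot be told apart from other sources. An effect of the compounds on class switching and a stronger response to DNFB in the control sample are both untested.

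Interferon-stimulated genes were higher in the 20(OH)D3 library than in the 25(OH)D3 library. The length trend was too small to be the whole source. Between the compounds its medians were 0.16 in the shortest and -0.06 in the longest decile. The list's median was 0.5398 after the trend was taken off. Against the higher fat share of the 20(OH)D3 sample as the whole source stand the list's medians against the control, 0.13 (interval -0.06 to 0.41) for 20(OH)D3, where adipocyte genes stood higher by 1.72, and -0.2659 (-0.37 to -0.15) for 25(OH)D3. Both rest on 1 control library and reuse the libraries compared, so this explanation stays open. A difference between the compounds and variation between mice stay open and were not tested.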
